A study of Mus musculus with 32 samples.

How the data were processed

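Bulk libraries of migratory dendritic cells and NK cells from tumour-draining lymph nodes were made with SMART-Seq v4, which primes poly(A) RNA, covers whole transcripts and does not mark strand, per the labels' protocols. Nodes were digested at 37C before sorting, per the labels' protocols. The authors deposited 1 table per library of whole-number read counts per gene, and STAR 2.5.2a, the mm10 build and DESeq2 1.26.0 are named in the submitters' processing notes. The counting tool is not given in the sources used here. Of 49315 gene rows, 345 carry no symbol and hold 0.0667% of counts. They were treated like other rows and entered library sizes and tests where they passed the low-count filter. Single-cell libraries were deposited as UMI counts per gene and cell, with mm10 and software version 3.0.2 per the file headers, 1 library per group from cells of 5 mice pooled in equal numbers. Cell types and clusters came from the authors' deposited cell table, whose lowest cell has 500 UMIs; how cells were named is not stated there. T cell receptor files deposited by the authors give cells per clonotype as counts and each clonotype's share as a fraction of the library's cells. Tables of enriched terms deposited by the authors give a p-value and an adjusted p-value per term and name groups by letters, which the sample descriptions assign to the groups; their tool, direction and background are not stated in the files. Deposited tables that list a count of 0 for every gene and enriched-term tables with no entries were not used.

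Groups came from the sample titles: 4 bulk groups per cell type with 3 libraries each, and 4 single-cell groups with 1 library each. Replicates of a group were compared first. The lowest chi-square per gene between 2 replicates was 4.82, well above sampling noise, so each was counted separately. The highest values, 132.4 and 122.6, were those of dendritic cell Ferritin-aCD4 replicate 3 against replicates 1 and 2 of its group. Bulk counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM scaling, robust quasi-likelihood fit over the 12 libraries of a cell type, 8 residual degrees of freedom) with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.472 in dendritic cells and 0.305 in NK cells. SEs are the absolute log2 difference divided by the square root of the quasi-likelihood F. Gene lists (38 lists, 711 entries, 708 matched) were tested with camera of limma 3.58.1 at a preset correlation and again with an estimated one, adjusted over the lists of a comparison. The tests, gene lists, cell type markers, rule for named genes and most alternatives were fixed before the data were examined; those added later are named in the closing section. In each main bulk comparison the rule took the 8 higher and 8 lower genes of largest fold past the threshold whose groups did not overlap (mean log2 CPM of at least 3), up to 4 members of each list that passed, and the 5 genes of smallest p in other comparisons. In single cells it took the 5 higher and 5 lower genes of largest CPM ratio with at least 50 UMIs, plus a fixed set of effector genes.

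The edgeR step was tested on simulated counts for MICB-iso against Ferritin-iso with 200 genes changed. It recovered 13% of 2-fold and 91% of 4-fold changes in dendritic cells (6 of 117 calls false) and 79% and 99% in NK cells (8 of 208). In each, 0 of 20 unchanged lists passed camera at the preset correlation. Genes were simulated independently of each other, so this check cannot speak to lists whose genes vary together.

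Single-cell matrices were read with scanpy 1.11.5 on python 3.11.15 (scipy 1.17.1, pandas 2.3.3, numpy 2.4.6). Of 2706, 3753, 2100 and 5336 barcodes (control vaccine + PBS, control vaccine + dox, MICB vaccine + PBS, MICB vaccine + dox), 2336, 3539, 1719 and 4381 were annotated, and 139, 287, 171 and 222 cells the authors called doublets were left out. UMIs were summed per library and cell class and given as CPM with exact 95% Poisson intervals; shares have exact Clopper-Pearson intervals, and both cover counting error only. With 1 library per group no test between groups was made. Classes of at least 50 cells in both libraries were compared, and lists were placed among 10000 random lists of the same size matched on expression. On simulated data the percentile of a changed list was 100, and 6 of 100 unchanged lists fell in the outer 5 percent. A class was compared between groups by name only where its own cells in no cluster had more leading markers of another class than of their own. Cells annotated as double-negative T cells or type 1 innate lymphoid cells had no markers fixed for this check, so their shares are not compared here. Cluster 18 mixes CD4 and B cells. The CD4 share of annotated cells and the Ifng ratio over control vaccine + dox are given with and without it, and the other CD4 values include it.

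Alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE size factors, no low-count filter, a fold minimum of 1.5, fits of the 6 libraries compared, pooled controls, the replicate number as a block, each library left out in turn, fry, other cell filters and UMI depths, and other definitions of a clonotype. Scrublet's automatic threshold called 10 of 11975 cells and was taken not to have worked; the 5% highest scores were removed in its place.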

Results

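The series followed a vaccine against MICB, a human stress-induced ligand of the activating receptor NKG2D, whose mouse gene is Klrk1. C57BL/6J mice were immunised with the MICB vaccine or a control vaccine and carried subcutaneous B16F10 melanoma tumours in which doxycycline (dox, 5 mg/kg) switched on MICB. Bulk RNA-seq covered migratory dendritic cells (mDC) and NK cells sorted from tumour-draining lymph nodes 2 days after induction, in 4 groups of 3 libraries per cell type. The groups were the control vaccine with an isotype antibody (Ferritin-iso) or with CD4 T cell depletion (Ferritin-aCD4), and the MICB vaccine with an isotype antibody (MICB-iso) or with depletion (MICB-aCD4). The 24 libraries held between 7829768 and 14956244 counts. The labels do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. Droplet single-cell RNA-seq and T cell receptor sequencing covered CD45+ cells of tumours 7 days after induction, with 1 library per group pooled from 5 mice, so no test between those groups was possible. After the cells the authors annotated as doublets were left out, 2197 cells of control vaccine + PBS, 3252 of control vaccine + dox, 1548 of MICB vaccine + PBS and 4159 of MICB vaccine + dox were used. Over all annotated cells, doublets included, the median depths were 3834, 4135, 6578 and 3315 unique molecular identifiers (UMIs).

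In migratory dendritic cells, MICB-iso libraries carried higher levels of interferon-stimulated genes than Ferritin-iso libraries, the comparison of the vaccines with CD4 cells present. Ifit3, an interferon-induced antiviral gene (chromosome 19, 34583531 to 34588731, plus strand), stood at 47.4 ± 8.85 CPM (counts scaled to a common library size; SD, n = 3) in MICB-iso and 4.70 ± 1.30 in Ferritin-iso, a log2 difference of 3.33 ± 0.40 (SE from edgeR's quasi-likelihood fit; mm10 coordinates throughout). Irf7, the transcription factor that amplifies type I interferon responses (chromosome 7, 141262706 to 141266481, minus strand), rose by 2.27 ± 0.28, and Cxcl9, a T cell-attracting chemokine of the interferon gamma response (chromosome 5, 92321347 to 92328079, minus strand), by 2.38 ± 0.35. Costimulatory Cd86 rose by 1.25 ± 0.23, the inhibitory ligand gene Pdcd1lg2 by 1.78 ± 0.30, and Ciita, the master regulator of MHC class II genes, by 1.17 ± 0.24. In all, 74 genes were higher and 1 was lower among 22258 tested with edgeR. Simulated data for this comparison recovered 13% of genes changed 2-fold and 91% of those changed 4-fold.

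Of the 36 interferon-stimulated genes measured in these cells, 8 rose, none fell and 28 did not pass; adjusted over the list alone, 23 rose. Beside Ifit3 and Irf7, Ifit2 (2.35 ± 0.40) and Oasl2 (1.90 ± 0.33) were among the genes that rose. Of 30 interferon gamma response genes 8 rose, and 17 did so adjusted over the list alone, among them the GTPase genes Iigp1 (2.44 ± 0.47), Tgtp2 (1.58 ± 0.26) and Tgtp1 (1.39 ± 0.24). Both lists also passed camera with an estimated correlation (edgeR and limma fits, adjusted p = 0.000233 and 0.0163). So did macrophage and monocyte markers, of which 3 of 18 rose (Fcgr1, 3.61 ± 0.65; Lyz2, 1.59 ± 0.32; Csf1r, 1.43 ± 0.30; adjusted p = 0.00732), and cDC1 markers, of which 2 of 18 rose (Ifi205, 2.46 ± 0.36; Naaa, 1.30 ± 0.25; adjusted p = 0.0244). Of 16 MHC class II presentation genes, Ciita alone rose, 11 did so adjusted over the list alone, and the median was 0.79; the call was lost with an estimated correlation (adjusted p = 0.0770). The chemokine gene Cxcl10 rose by 1.77 ± 0.34, and Ifitm1 (2.48 ± 0.38), Ly6i (2.41 ± 0.34), P2ry13 (2.37 ± 0.34), Il1rn (1.69 ± 0.27), Stat4 (1.71 ± 0.26), Cd200 (1.11 ± 0.22), Serpina3g (1.09 ± 0.21), Pilra (1.94 ± 0.26) and Klra9 (3.79 ± 0.63) rose as well. Tgtp1 and Tgtp2, Ifi205 and its neighbours, and Klra9 belong to families of near-identical copies that can share reads, so their separate values are uncertain. Klra9 (0.46, 0.62 and 0.82 CPM) and Fcgr1 (0.15, 0.73 and 1.55 CPM) were very low in Ferritin-iso, which makes the size of their rise uncertain. Of 12 alpha-beta T cell markers none passed over all genes, 5 were lower adjusted over the list alone, and the median was -0.72 (adjusted p = 0.140 with an estimated correlation). Ifit3 was 31.9 ± 9.83 CPM in Ferritin-aCD4 and 21.7 ± 12.1 CPM in MICB-aCD4, so the Ferritin-iso libraries held the lowest level of the 4 groups. With the T cell marker score as a covariate 0 genes passed (edgeR; 7 of the 8 called interferon-stimulated genes kept an unadjusted p under 0.05), whereas DESeq2 called 335 genes and limma voom 473. Leaving out 1 library gave between 4 genes (without Ferritin-iso replicate 2) and 457 (without Ferritin-aCD4 replicate 3), 8 of the 12 left-out libraries moved the count by over 1.5 times, and leaving out both libraries with the fewest detected genes (Ferritin-aCD4 replicate 3 and MICB-iso replicate 3) gave 266.

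**Figure D1:**
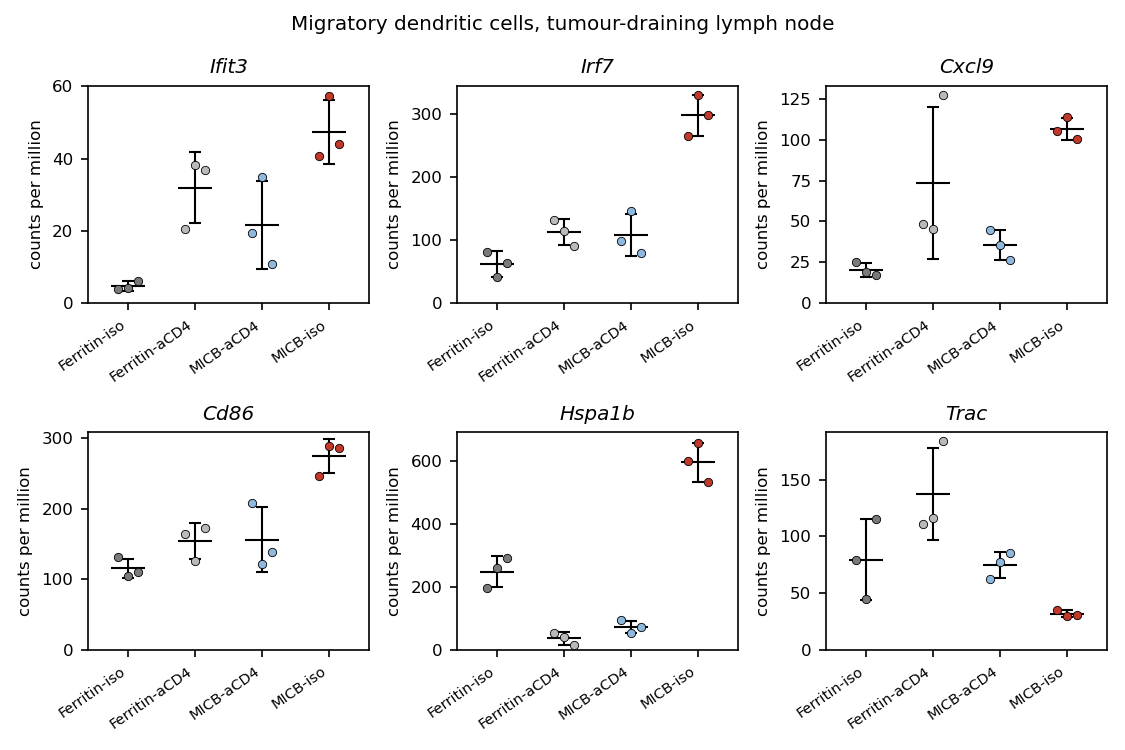
CPM of 6 genes in migratory dendritic cells, 1 point per library, with the mean (horizontal line) and SD (bars) of the 3 libraries of each group on linear axes. Ifit3 was lowest in Ferritin-iso (4.70 CPM) and highest in MICB-iso (47.4 CPM), Hspa1b was higher in both isotype groups, and Trac was lowest in MICB-iso (31.7 CPM).

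MICB-iso was set against MICB-aCD4 to compare the 2 antibodies after the MICB vaccine. Migratory dendritic cells of MICB-iso held more transcripts of the inducible heat shock genes Hspa1b (3.04 ± 0.37) and Hspa1a (2.73 ± 0.30), with Hspa1b at 597.5 ± 62.5 CPM against 72.5 ± 19.3. The ribonucleotide reductase gene Rrm2 rose by 1.85 ± 0.29, and the interferon gamma response genes Tgtp1 and Ifi47 by 1.43 ± 0.24 and 1.23 ± 0.22. Cd1d1, the gene of a lipid-presenting molecule, was 2.40-fold higher. Klra9, of the Ly49 receptor family, rose by 4.08 ± 0.65, from very low values of 0.40, 0.82 and 0.37 CPM to 6.13, 8.37 and 12.1. The genes that fell were Xpa (-1.84 ± 0.32), a nucleotide excision repair factor, Pithd1 (-1.83 ± 0.29), Scand1 (-1.71 ± 0.30), Vapa (-1.34 ± 0.23) and Dcun1d5 (-1.33 ± 0.23). In all, 7 genes were higher and 5 lower. None of the 36 interferon-stimulated genes passed over all genes by edgeR, 14 rose adjusted over the list alone, and the median was 0.69 (adjusted p = 0.00242 with an estimated correlation). Of 30 interferon gamma response genes 2 rose, and adjusted over the list alone 14 rose and 1 fell (adjusted p = 0.0483 with an estimated correlation). Of 35 proliferation genes 1 rose, Rrm2, and 3 did so adjusted over the list alone, with a median of 0.59; this call was lost with an estimated correlation (adjusted p = 0.10). Alpha-beta T cell markers had a median of -1.07, with 0 of 12 past over all genes and 8 lower adjusted over the list alone (adjusted p = 0.0802 with an estimated correlation). Rrm2 and the 5 genes that fell went the same way between antibodies after the control vaccine, without passing the threshold. There Rrm2 stood at 44.6, 34.1 and 64.7 CPM in Ferritin-iso against 20.2, 16.9 and 11.8 in Ferritin-aCD4. Xpa stood at 6.6, 8.6 and 9.5 against 14.0, 16.7 and 21.3. Tgtp1 and Ifi47 went the other way. Hspa1a and Hspa1b are near-identical neighbouring copies on chromosome 17, so their separate values are uncertain. The count ranged from 2 genes (without Ferritin-iso replicate 1, or MICB-iso replicate 2 or 3) to 183 (without Ferritin-aCD4 replicate 3), DESeq2 called 260 and limma voom 189, and with the T cell marker score as a covariate edgeR called 0.

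Against the 3 control groups together, the comparison the series design names, MICB-iso dendritic cells had 79 genes higher and 18 lower. Hspa1b (2.79 ± 0.25) and Hspa1a (2.23 ± 0.21) rose, as did Iigp1 (2.32 ± 0.34), Kdr (1.82 ± 0.32), which encodes a VEGF receptor, Ifi205 (1.76 ± 0.26) and Ifit2 (1.74 ± 0.29). Ifi204, of the same DNA-sensor family as Ifi205, rose by 1.71 ± 0.26. Of 36 interferon-stimulated genes 11 rose, or 22 adjusted over the list alone, among them Ifit2, Irf7 (1.71 ± 0.20), Oas2 (1.71 ± 0.33), Ifit3 (1.68 ± 0.27) and Usp18 (1.12 ± 0.16). Of 30 interferon gamma response genes 10 rose, and adjusted over the list alone 16 rose and 1 fell. Both lists held with an estimated correlation (adjusted p = 0.000546 and 0.0205), as did macrophage and monocyte markers, of which 0 of 18 passed over all genes and 6 did adjusted over the list alone (adjusted p = 0.0205). The costimulatory genes Cd86 (0.97 ± 0.18) and Cd80 (0.87 ± 0.18) rose, as did the checkpoint ligand genes Cd274 (1.06 ± 0.20) and Pdcd1lg2 (1.30 ± 0.22), Cxcl9 (1.5 ± 0.25) and the chaperone gene Hsph1 (1.63 ± 0.26). The neutrophil gene S100a8 passed too (4.13 ± 0.73), but stood at 29.2, 1.05 and 4.84 CPM in the 3 MICB-iso libraries and at 2.16 ± 0.90 without MICB-iso replicate 1 (edgeR adjusted p = 0.346). Of 16 MHC class II presentation genes Ciita rose (1.00 ± 0.18), with 6 adjusted over the list alone (adjusted p = 0.122 with an estimated correlation).

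Genes that fell in MICB-iso dendritic cells included T cell transcripts. Trac, the T cell receptor alpha constant gene, fell by 1.56 ± 0.26 on the log2 scale, from group means of 137.2, 79.5 and 74.9 CPM in Ferritin-aCD4, Ferritin-iso and MICB-aCD4 to 31.7. Lat (-1.52 ± 0.27), Cd3g (-1.41 ± 0.26), Trbc1 (-1.31 ± 0.23) and Trbc2 (-1.23 ± 0.24), all parts of T cell receptor signalling, fell too, as did Cd40lg (-1.71 ± 0.35), Sit1 (-1.72 ± 0.36), Skap1 (-1.09 ± 0.20), Icos (-1.03 ± 0.19), Il7r (-0.83 ± 0.18), Rab4a (-1.84 ± 0.36), Rgcc (-1.29 ± 0.28) and Hspb6 (-1.15 ± 0.24). Of 12 alpha-beta T cell markers 4 fell and 8 did so adjusted over the list alone, with a median of -1.12 (adjusted p = 0.0520 with an estimated correlation). Cd4 itself, the antibody target, differed by 0.04 ± 0.22 (edgeR adjusted p = 0.968) in these sorted dendritic cells. The count ranged from 5 (without MICB-iso replicate 2) to 453 (without Ferritin-aCD4 replicate 3) and was 215 without both libraries of fewest detected genes. With the T cell marker score as a covariate edgeR called 0 genes and Kdr turned to -0.04, while DESeq2 called 475 genes and limma voom 537. That score is the mean of the 12 alpha-beta T cell markers, so the covariate is circular for T cell transcripts and cannot decide about them.

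In the control vaccine arm few dendritic cell genes passed the threshold between the antibodies: 2 were higher and 1 lower in Ferritin-iso than in Ferritin-aCD4. Hspa1b (2.81 ± 0.37) and Hspa1a (2.29 ± 0.29) were higher and Ifit3 fell by 2.76 ± 0.39. The next genes by p, Ly6i (-1.92 ± 0.34) and Cfp (-1.41 ± 0.24), which encodes properdin, did not pass (edgeR adjusted p = 0.0691 for both). Of 36 interferon-stimulated genes 14 fell adjusted over the list alone, with a median of -0.40 (adjusted p = 0.0289 with an estimated correlation). Alpha-beta T cell markers had a median of -0.90 with 7 of 12 lower adjusted over the list alone, and NK identity genes a median of 1.28 with 6 of 12 higher and 1 lower (adjusted p = 0.102 and 0.0549 with an estimated correlation). DESeq2 called 126 genes and limma voom 76, and leaving out 1 library, Ferritin-aCD4 replicate 1, 2 or 3 or MICB-iso replicate 3 gave 23, 20, 7 and 6.

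With CD4 cells depleted, edgeR called 0 dendritic cell genes between MICB-aCD4 and Ferritin-aCD4, with 1388 genes at an unadjusted p under 0.05; DESeq2 called 5, limma voom 2 and edgeR without a low-count filter 54. The genes of smallest p, none of which passed, were Tnfsf8 (-1.92 ± 0.41), Rgl1 (1.21 ± 0.26), Rora (-1.17 ± 0.26), Arhgap22 (2.40-fold higher) and Neurl3 (-0.92 ± 0.22), each with an edgeR adjusted p of 0.761.

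The interaction of vaccine and antibody was tested in both cell types. In dendritic cells 8 genes passed, all with a larger vaccine difference under the isotype antibody. They included Ifit3 (3.89 ± 0.54), Cxcl9 (3.43 ± 0.48), Ly6i (3.14 ± 0.47), Ifi205 (3.13 ± 0.49) and Irf7 (2.33 ± 0.38). In Ferritin-aCD4 replicates 1, 2 and 3, Cxcl9 stood at 48.5, 45.1 and 127.5 CPM and Ly6i at 79.5, 62.8 and 171.0. Ifi205 was also highest in replicate 3, whereas Ifit3 was not and Irf7 was lowest there. The interaction values of Cxcl9, Ly6i and Ifi205 thus rest in part on that library. Of 36 interferon-stimulated genes 2 passed and 19 did so adjusted over the list alone (adjusted p = 0.000775 with an estimated correlation). The lists of interferon gamma response genes, cDC1, cDC2, and macrophage and monocyte markers passed as well (adjusted p = 0.0345, 0.0329, 0.0345 and 0.0200). In NK cells 10 genes passed, each with a more positive vaccine difference under the isotype antibody, among them Ifit3 (1.43 ± 0.21), Usp18 (1.21 ± 0.18), which restrains interferon receptor signalling, the granzyme genes Gzmc (1.19 ± 0.18) and Gzmb (1.14 ± 0.13), and the transcription factor gene Irf8 (0.90 ± 0.10). For Irf8 the difference that passed was the fall under anti-CD4 (-0.59 ± 0.07), with 0.30 ± 0.07 under the isotype antibody. Of 36 interferon-stimulated genes 3 passed and 23 did so adjusted over the list alone, of 35 proliferation genes 0 and 20, and of 29 interferon gamma response genes 1 and 8 (adjusted p = 0.00128, 0.0348 and 0.0120 with an estimated correlation). DESeq2 called 138 and 66 genes in the dendritic and NK cells, and edgeR with the T cell marker score as a covariate 0 and 3; the edgeR counts ranged from 3 (without MICB-aCD4 replicate 3 or MICB-iso replicate 2) to 62 (without Ferritin-aCD4 replicate 3) in dendritic cells and from 3 (without any of 6 libraries) to 16 (without Ferritin-aCD4 replicate 1) in NK cells.

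In NK cells, MICB-iso libraries held more interferon-stimulated transcripts than Ferritin-iso libraries. Hspa1a (1.73 ± 0.19), Hspa1b (1.57 ± 0.17) and Hsph1 (1.08 ± 0.10) rose, from a stress list of 23 genes of which 4 rose and which did not pass as a whole (adjusted p = 0.594 by camera with an estimated correlation). Ifit3 rose by 1.30 ± 0.15, from 17.6 ± 1.15 to 43.3 ± 3.36 CPM, with Ifit1 (1.27 ± 0.20), Ifi27l2a (1.30 ± 0.23), Ifitm1 (1.19 ± 0.17; chromosome 7, 140967221 to 140969825, plus strand) and Ifitm2 (1.14 ± 0.21). Gzmb, the main cytotoxic granule protease (chromosome 14, 56258856 to 56262260, minus strand), rose by 0.67 ± 0.09, from 886.7 ± 51.3 to 1413 ± 159 CPM, and Gzmc by 1.06 ± 0.13. Il7r fell by 0.52 ± 0.08, the voltage-gated proton channel gene Hvcn1 by 0.59 ± 0.10 and the cold-inducible RNA-binding protein gene Cirbp by 0.62 ± 0.09. In all, 35 genes were higher and 8 lower among 20453 tested.

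Of 36 interferon-stimulated genes measured in NK cells 12 rose, or 23 adjusted over the list alone, including Usp18 (0.95 ± 0.13) and Oasl1 (0.90 ± 0.14). Of 29 interferon gamma response genes 2 rose, Igtp (0.77 ± 0.13) and Cxcl10 (0.77 ± 0.14), or 11 adjusted over the list alone. Of 35 proliferation genes 3 rose (Cks1b, 0.64 ± 0.11; Mcm2, 0.74 ± 0.12; Stmn1, 0.62 ± 0.11), or 25 adjusted over the list alone. These lists held with an estimated correlation (adjusted p = 0.000789, 0.0181 and 0.0193). Of 24 cytotoxic effector genes 2 rose, both granzymes, and adjusted over the list alone 6 rose and 2 fell; the list did not pass camera (adjusted p = 0.0780). Of 29 MYC target and ribosome biogenesis genes 0 passed over all genes and 9 rose adjusted over the list alone (adjusted p = 0.147 with an estimated correlation). Tnfrsf9, which encodes the costimulatory receptor 4-1BB, rose by 0.55 ± 0.10, Sco1 by 1.21 ± 0.22 and Hspa8 by 0.40 ± 0.07, and Tmem106b (-0.89 ± 0.12), Pgm2l1 (-0.66 ± 0.13), Emb (-0.48 ± 0.06), Serinc3 (-0.39 ± 0.08) and Cytip (-0.34 ± 0.06) fell. B cell markers had a median of 0.50, with 5 of 15 higher adjusted over the list alone (adjusted p = 0.205 with an estimated correlation). Klrk1, the receptor gene for MICB, differed by -0.06 ± 0.08 (edgeR adjusted p = 0.926) and Ncr1 by 0.18 ± 0.09 (0.668). The count ranged from 11 (without MICB-iso replicate 3) to 122 (without Ferritin-aCD4 replicate 1) and was 226 without both libraries of fewest detected genes (Ferritin-aCD4 replicate 1 and Ferritin-iso replicate 1); DESeq2 called 227 genes and limma voom 194, and edgeR with the T cell marker score as a covariate 21.

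**Figure D2:**
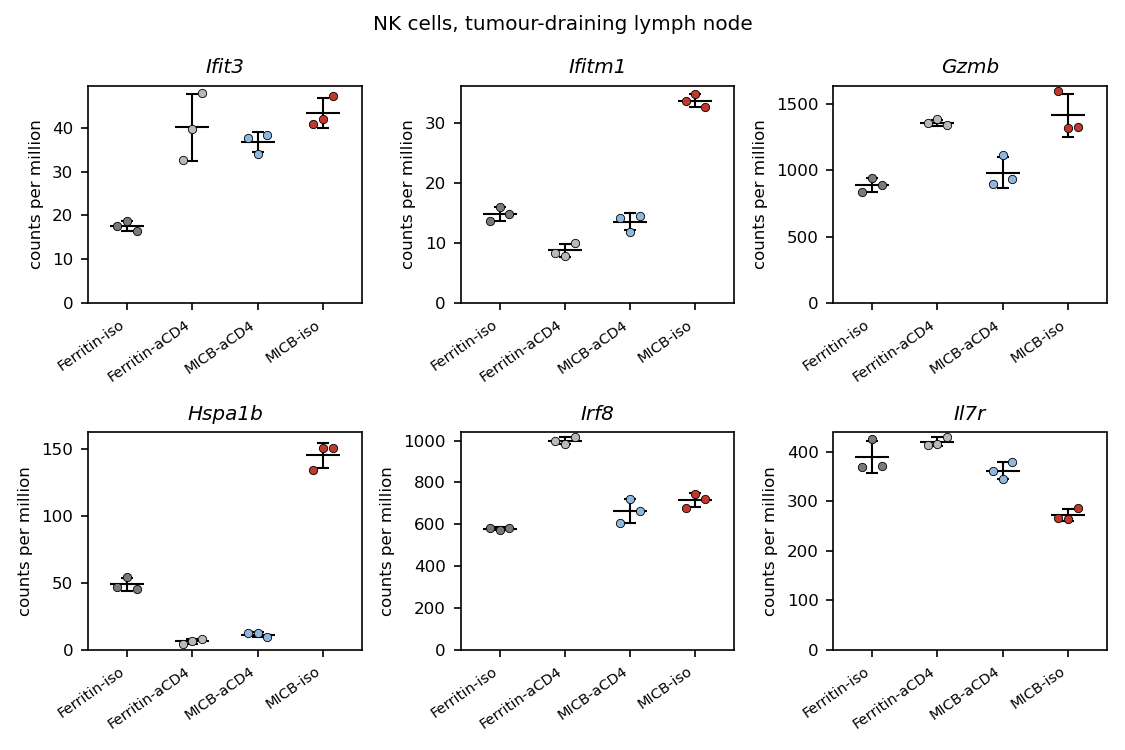
CPM of 6 genes in NK cells, 1 point per library, with the mean (horizontal line) and SD (bars) of the 3 libraries of each group on linear axes. Ifit3 was lowest in Ferritin-iso (17.6 CPM), Hspa1b was higher in both isotype groups than in the anti-CD4 groups, and Il7r was lowest in MICB-iso (272.5 CPM).

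After the MICB vaccine, NK cells of the isotype group held more chaperone gene transcripts than those of the anti-CD4 group. MICB-iso exceeded MICB-aCD4 by 3.69 ± 0.19 for Hspa1b, 3.64 ± 0.22 for Hspa1a, 1.09 ± 0.10 for Hsph1 and 0.47 ± 0.07 for Hspa8, all of which encode chaperones. Ifitm1 (1.32 ± 0.17), Upp1 (0.67 ± 0.11) and Cd48 (0.43 ± 0.07), a ligand of the NK receptor 2B4, were also higher. Cd4 was higher by 1.27 ± 0.18, at 85.4 ± 16.2 CPM against 35.5 ± 5.21. Cirbp (-0.81 ± 0.09), Tmem106b (-0.71 ± 0.12), Rnf138 (-0.58 ± 0.09), the glucocorticoid-induced gene Tsc22d3 (-0.51 ± 0.07) and the interferon gamma receptor gene Ifngr1 (-0.41 ± 0.07) fell. In all, 9 genes were higher and 5 lower. None of 36 interferon-stimulated genes passed over all genes by edgeR and 6 rose adjusted over the list alone; of 35 proliferation genes 0 and 15 did, and of 29 interferon gamma response genes 1 and 3 (adjusted p = 0.0412 with an estimated correlation for each list). Of 23 early response and dissociation stress genes 4 rose, namely the 4 chaperone genes above, and adjusted over the list alone 7 rose and 3 fell (adjusted p = 0.168 with an estimated correlation). The count ranged from 4 (without MICB-iso replicate 2) to 47 (without Ferritin-aCD4 replicate 1); DESeq2 called 106 genes and limma voom 297.

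Against the 3 control groups together, MICB-iso NK cells had 63 genes higher and 66 lower. Hspa1b (3.27 ± 0.13), Hspa1a (3.17 ± 0.15), Ifitm1 (1.48 ± 0.13), Hsph1 (1.34 ± 0.08) and the spermidine synthase gene Srm (1.23 ± 0.26) rose. Cell cycle genes that rose included Ccne1 (0.97 ± 0.19), Uhrf1 (0.76 ± 0.12), Tyms (0.65 ± 0.11) and Birc5 (0.63 ± 0.11). Gzmc (0.68 ± 0.10), Gzmb (0.42 ± 0.07), the cytokine-induced gene Cish (0.68 ± 0.11), Tbx21 (0.46 ± 0.10), which encodes T-bet, and Cd160 (0.39 ± 0.07) rose. Ccr7 (-0.95 ± 0.20), the lymph node homing receptor gene, Tigit (-0.53 ± 0.11), Il7r (-0.52 ± 0.07), Ifngr1 (-0.60 ± 0.06), Tsc22d3 (-0.60 ± 0.06), Jak1 (-0.41 ± 0.06), Rora (-0.61 ± 0.11), Emb (-0.59 ± 0.05), Rab27a (-0.45 ± 0.09) and Cirbp (-0.98 ± 0.08) fell. Coq8a (-0.89 ± 0.17), Hvcn1 (-0.78 ± 0.09) and Pdk2 (-0.69 ± 0.15) fell as well. Of 35 proliferation genes 6 rose, or 24 adjusted over the list alone, and of 36 interferon-stimulated genes 6 rose, or 15 adjusted over the list alone (adjusted p = 0.0291 and 0.0118 with an estimated correlation). Of 29 interferon gamma response genes 3 rose and of 29 MYC target genes 3, or 8 and 11 adjusted over the list alone; both calls were lost with an estimated correlation (adjusted p = 0.0567 and 0.108). The 13 mitochondrial transcripts had a median of -0.44, with 10 lower adjusted over the list alone (adjusted p = 0.690 with an estimated correlation). The count ranged from 21 (without MICB-iso replicate 3) to 302 (without Ferritin-aCD4 replicate 1) and was 766 without both libraries of fewest detected genes; DESeq2 called 451 genes and limma voom 1004.

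In the control vaccine arm, CD4 depletion was accompanied by higher interferon-stimulated transcripts in NK cells. Ferritin-iso had 6 genes higher and 50 lower than Ferritin-aCD4, with Hspa1b (2.98 ± 0.20) and Hspa1a (2.42 ± 0.22) higher and Irf8 (-0.79 ± 0.07), Ifngr1 (-0.72 ± 0.07) and Cirbp (-0.88 ± 0.09) lower. Of 36 interferon-stimulated genes 7 fell, or 24 adjusted over the list alone, with a median of -0.54 (adjusted p = 0.00382 with an estimated correlation). B cell markers had a median of -0.62 with 1 of 15 lower, or 7 adjusted over the list alone, and alpha-beta T cell markers a median of -0.50 with 9 of 12 lower adjusted over the list alone (adjusted p = 0.152 and 0.230 with an estimated correlation). Between MICB-aCD4 and Ferritin-aCD4, NK cells had 1 gene higher and 19 lower, the latter including Emb (-0.66 ± 0.06), Ifngr1 (-0.65 ± 0.07), Irf8 (-0.59 ± 0.07), Hvcn1 (-0.82 ± 0.10) and the NK lectin receptor gene Klrb1b (-0.56 ± 0.07). Without Ferritin-iso replicate 2 the first count was 25, and with the T cell marker score as a covariate 2; the second ranged from 5 (without MICB-aCD4 replicate 1) to 32 (without Ferritin-iso replicate 1).

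**Figure D3:**
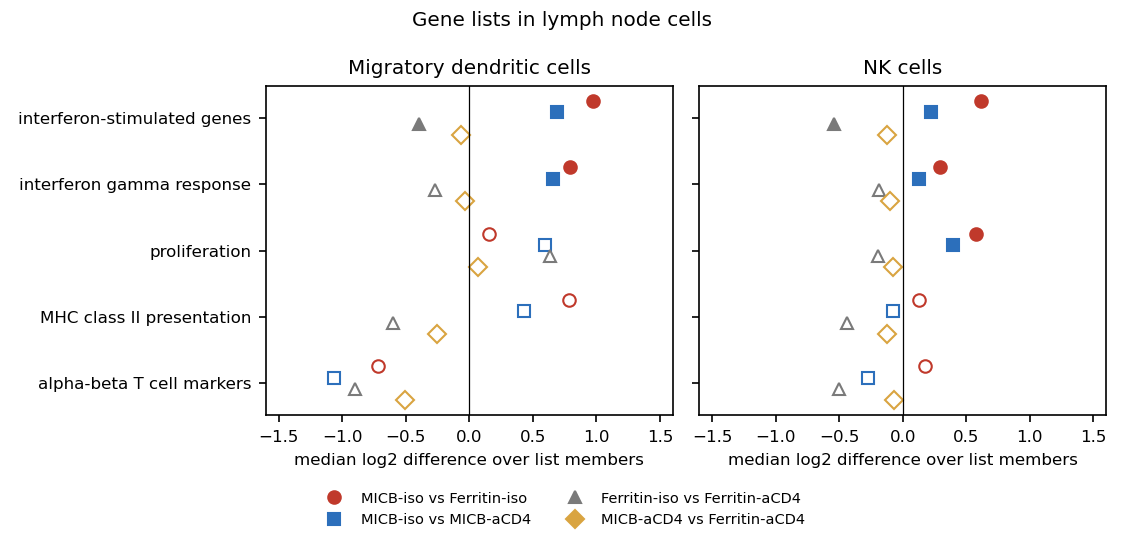
Median log2 difference over the members of 5 gene lists in migratory dendritic cells and NK cells, with 1 marker shape per comparison and filled markers where camera with an estimated correlation passed an adjusted p of 0.05. Interferon-stimulated genes were above 0 in MICB-iso against Ferritin-iso (dendritic cells 0.97, NK cells 0.62) and below 0 in Ferritin-iso against Ferritin-aCD4 (-0.40 and -0.54).

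In the authors' deposited table of enriched terms for Ferritin-iso and MICB-iso dendritic cells, 11 of 1617 terms had an adjusted p under 0.05, led by immune system process (47 of 384 genes, adjusted p = 7.78e-09) and cellular response to interferon-beta (12 of 39 genes, 2.59e-08). In the authors' deposited table for MICB-iso and MICB-aCD4 dendritic cells, the interferon-beta term held 8 of 39 genes (1.3e-05). In the authors' deposited table for Ferritin-iso and MICB-iso NK cells, response to virus (5 of 54 genes) and defense response to virus (6 of 138 genes) each had an adjusted p of 7.2e-09.

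In tumours, the MICB vaccine + dox library held larger shares of NK and T cells than each of the other 3 libraries. NK cells were 8.37% of annotated CD45+ cells (95% exact Clopper-Pearson interval 7.54 to 9.25) in MICB vaccine + dox, 2.64% (2.12 to 3.26) in control vaccine + dox, 3.10% (2.29 to 4.09) in MICB vaccine + PBS and 3.28% (2.57 to 4.11) in control vaccine + PBS. CD8 T cells were 14.7% (13.7 to 15.9) against 5.63% (4.86 to 6.48), 5.68% (4.58 to 6.96) and 5.23% (4.34 to 6.25) in the same order. Cells annotated as CD4 T cells, regulatory T cells included, were 18.3% (17.2 to 19.6) against 4.58% (3.89 to 5.36), 4.39% (3.43 to 5.54) and 2.96% (2.29 to 3.76). The CD4 class includes part of cluster 18, in which B cell genes (Ms4a1, Cd79b) outnumbered CD4 genes (Cd40lg) among the leading genes of the cluster as a whole, B cells included. Without that cluster the CD4 shares were 14.7%, 4.34%, 3.85% and 2.84%, and cluster 5, the largest cluster of the CD4 class in every library, took 9.28%, 2.55%, 1.94% and 1.05%. Cluster 18 itself took 4.35%, 1.6%, 0.904% and 3.73%. These intervals cover counting error only, and 1 pooled library per group leaves the spread between mice unmeasured.

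Dendritic cell classes took smaller shares in MICB vaccine + dox. Conventional type 1 dendritic cells were 0.409% (0.238 to 0.654) against 1.41% in control vaccine + dox, 3.23% in MICB vaccine + PBS and 1.05% in control vaccine + PBS. Conventional type 2 cells were 1.32% against 4.43%, 6.40% and 3.91%, the class the authors call mregDC 0.601% against 1.97%, 4.20% and 2.00%, and plasmacytoid cells 1.35% against 2.28%, 5.56% and 2.78%. Macrophage and monocyte classes were compared by cluster number, because some of their clusters had more leading genes of another class than of their own. Cluster 14, annotated mostly as monocytes, took 7.41% in MICB vaccine + dox against 1.23%, 0.452% and 0.819%, and since 311 of its 386 cells, doublets included, came from that library, it may reflect the library and not a cell type. Clusters 22 and 17, annotated mostly as macrophages, took 0.216% and 0.914% against 3.6% and 4.55% in control vaccine + dox, 6.01% and 4.39% in MICB vaccine + PBS and 2.18% and 4.69% in control vaccine + PBS. Clusters 1 and 10, annotated mostly as B cells, took 0.505% and 0.625% against 8.70% and 8.00%, 5.81% and 1.16%, and 14.2% and 6.74%. For cluster 10 the intervals of the 2 MICB vaccine libraries overlapped (0.409 to 0.915 and 0.691 to 1.83). Shares of 1 library sum to the whole, so a larger share of one class lowers all others.

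**Figure D4:**
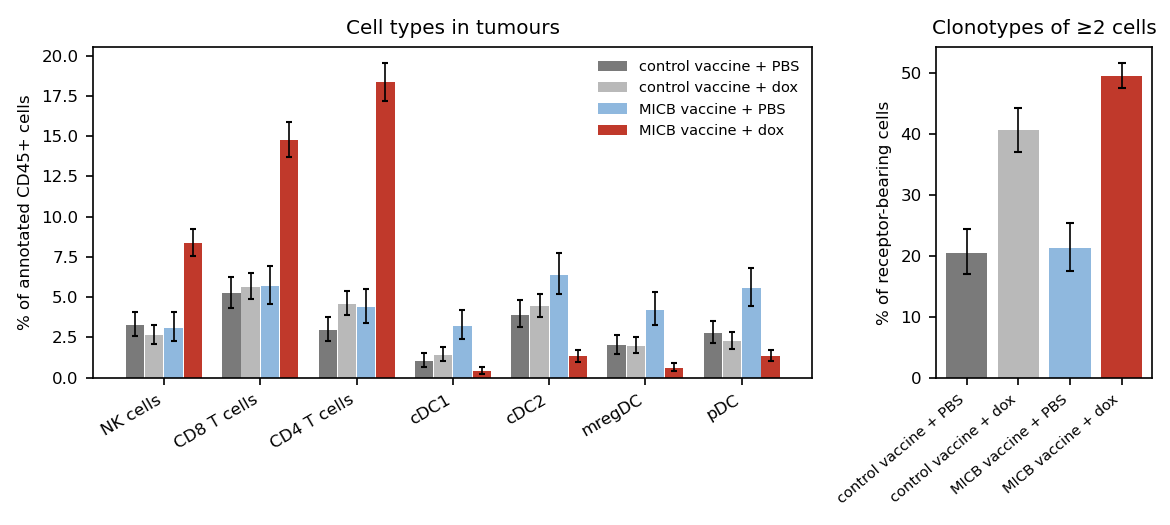
Left, share of annotated CD45+ tumour cells taken by 7 cell classes in the 4 single-cell libraries, with 95% exact binomial intervals. Right, share of receptor-bearing cells in clonotypes of at least 2 cells. NK (8.37%), CD8 (14.7%) and CD4 (18.3%) bars were highest in MICB vaccine + dox, and the dendritic cell bars lowest.

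Within tumour NK cells, MICB vaccine + dox was set against control vaccine + dox (348 and 86 cells). Ifng stood at 245.4 CPM (95% Poisson interval 220.9 to 271.8) against 135.2 (100.7 to 177.8), Klrk1 at 571.0 (533.4 to 610.6) against 408.3 (346.4 to 478.2), and Rgcc, a cell cycle regulator gene, at 138.4 against 26.5. Tcf7, the gene of the stem-like lymphocyte factor TCF1, had a log2 ratio of 1.17 (interval 0.50 to 1.91). Granule genes were lower, with log2 ratios of -0.36 for Gzma, -1.20 for Gzmb, -0.89 for Prf1, which encodes perforin, and -3.13 for Gzmc. Ccl5 was lower by -0.53, and the MHC class II genes Cd74 and H2-Aa, which B cells and myeloid cells express at high levels, by -3.76 and -3.64. The MHC class II list of NK cells lay at percentile 0.0 of matched random lists, as it did in the T cell classes, so transcripts of other cells are not separated from those of NK cells here. Cytotoxic effector genes as a list lay at percentile 0.720 of 10000 matched random lists in this comparison and at 77.2 against control vaccine + PBS. NK_Xcl1 cells were 79.3% of NK cells against 69.8% in control vaccine + dox, and cluster 13 was the largest NK cluster in every library. MICB vaccine + PBS held 48 NK cells, under the minimum of 50, and was not compared.

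Tumour CD8 T cells of MICB vaccine + dox held more transcripts of Il7r, Cxcr3 and Tcf7 and fewer of granule genes than those of control vaccine + dox (613 and 183 cells). The interleukin 7 receptor gene Il7r had a log2 ratio of 2.62 (2.13 to 3.14), the chemokine receptor gene Cxcr3 2.21 (1.76 to 2.70), Rgcc 2.21 (1.82 to 2.61), Tnfsf14 2.35 (1.36 to 3.53) and Tcf7 1.55 (1.04 to 2.09). Ccl5 (1.08), Ifng (0.63), Xcl1 (0.57) and Klrk1 (0.54) were higher as well, while Gzmb (-2.01), Prf1 (-1.78), Gzma (-0.94) and Mki67 (-0.60) were lower. The checkpoint receptor gene Pdcd1 (-0.08, interval -0.23 to 0.07) and the exhaustion factor gene Tox (0.11, interval -0.09 to 0.31) did not differ detectably at this depth. Against MICB vaccine + PBS, Crtam (3.20), Csf1 (3.02), Cd69 (2.32) and Ifng (1.31) were higher. Proliferation genes lay at percentile 0.0 of matched random lists in all 3 comparisons, and cells annotated as proliferating were 5.38% of CD8 cells against 21.3%, 18.2% and 18.3%. The CD8 cells of the other libraries also carried myeloid transcripts, with H2-Aa at 1041 CPM in control vaccine + dox against 7.70 in MICB vaccine + dox, and more UMIs per cell (9005 against 5084). Cluster 8 was the largest CD8 cluster in these 2 libraries and in MICB vaccine + PBS, and cluster 9 in control vaccine + PBS. Effector cells were 64.6% of CD8 cells in MICB vaccine + dox against 39.9% in control vaccine + dox, and exhausted cells 30.0% against 38.8%. A change of subset mix was not separated here from a change within subsets, nor was it in the NK and CD4 classes.

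In cells annotated as CD4 T cells Ifng, the gene of interferon gamma, stood at 412.9 CPM (391.1 to 435.6) in MICB vaccine + dox against 54.6 (38.2 to 75.5) in control vaccine + dox, 158.8 in MICB vaccine + PBS and 319.1 in control vaccine + PBS. The order against control vaccine + PBS was not stable, with a log2 ratio of 0.37 that turned to -0.26 with cells thinned to 1000 UMIs. Without cluster 18 the log2 ratio over control vaccine + dox was 2.80 (2.31 to 3.32). Tnfsf11, which encodes RANKL, had a log2 ratio of 3.07 (2.34 to 3.92), Zbtb7b, the gene of the CD4 lineage factor ThPOK, 3.26 (1.69 to 5.56), Lta 2.95 (1.36 to 5.25) and Klrk1 1.35 (0.90 to 1.82). Foxp3 (-1.29), Tox (-1.58) and Gzmb (-1.49) were lower. Pdcd1 had a log2 ratio of -0.54, which turned to 0.44 with cells thinned to 1000 UMIs. Regulatory T cells were 7.08% of the class against 18.8% in control vaccine + dox, 19.1% in MICB vaccine + PBS and 21.5% in control vaccine + PBS. MHC class II and macrophage marker lists lay at percentile 0.0 of matched random lists in CD8 and CD4 cells in every comparison.

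T cell receptors were read in 2194 cells of MICB vaccine + dox, 728 of control vaccine + dox, 451 of MICB vaccine + PBS and 486 of control vaccine + PBS. Cells in clonotypes of at least 2 cells were 49.6% (47.5 to 51.8), 40.7% (37.1 to 44.3), 21.3% (17.6 to 25.4) and 20.6% (17.1 to 24.4). Of the receptor-bearing cells 343, 313, 186 and 167 carried an annotation other than T cells, of which 100, 205, 114 and 104 were doublets. A further 361, 27, 98 and 77 lay outside the authors' annotation, and 191, 12, 26 and 10 of these were in clonotypes of at least 2 cells. All these cells, doublets included, stayed in the shares above. Among annotated T cells alone the shares were 48.9%, 37.9%, 10.8% and 18.2%. With each library thinned to 451 cells the shares were 37.0%, 38.2%, 21.3% and 19.9%, and the ranges of the dox libraries over 1000 draws (32.4 to 41.7 and 34.8 to 41.2) overlapped. The largest clonotypes held 77, 61, 7 and 11 cells, and the most frequent annotation in each was exhausted CD8 T cells (58, 22, 3 and 7 cells). In control vaccine + PBS a second clonotype also held 11 cells, most often annotated as doublets (5 cells). In MICB vaccine + dox, expanded clonotypes held 89.7% of exhausted CD8 cells with a receptor, 67.8% of CD4 cells and 53.3% of effector CD8 cells. These shares were 85.9%, 56.8% and 37.9% in control vaccine + dox and 60.9%, 34.3% and 2.94% in MICB vaccine + PBS. In control vaccine + PBS they were 80.8%, 14.8% and 23.2%. They were not thinned to equal cell numbers. Across libraries, 6 clonotypes were seen in more than 1.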

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

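The interaction tests were planned. All split counts, the test of Ferritin-iso expression, those of dilution by T cell RNA, of libraries with few detected genes, of tissue dissociation and of a lower dendritic cell share were chosen after the results were seen.

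The vaccine effect differed between isotype and anti-CD4 libraries for 8 genes in dendritic cells, by 3.89 (log2) for Ifit3, 3.43 for Cxcl9, 3.14 for Ly6i, 3.13 for Ifi205 and 2.33 for Irf7. In NK cells it differed for 10 genes, by 0.90 for Irf8, 1.14 for Gzmb, 1.21 for Usp18, 1.43 for Ifit3 and 1.19 for Gzmc. Part of the receptor-bearing cells counted above lay in barcodes outside the authors' annotation. They were 77 in control vaccine + PBS, 27 in control vaccine + dox, 98 in MICB vaccine + PBS and 361 in MICB vaccine + dox. Among cells annotated as B cells, 61.8% of those in cluster 6 (68 of 110) carried a T cell receptor, against 0.432%, 0.460% and 0.800% in clusters 1, 10 and 18. By library, 56.2% of B-annotated cells of MICB vaccine + dox (95 of 169) carried one. The shares were 1.66% in control vaccine + PBS, 0.993% in control vaccine + dox and 4.10% in MICB vaccine + PBS.

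The first pattern is the higher interferon-stimulated transcripts of MICB-iso dendritic cells over Ferritin-iso. Against a cause in low Ferritin-iso libraries alone, the list's median over the anti-CD4 groups was still 0.66 (32 of 36 genes positive, adjusted p = 0.00225 by camera with an estimated correlation), although the 8 called genes fell from a median of 2.08 to 1.10 and 1 passed; against libraries with few detected genes as the cause, the median without the 2 was 1.01 (35 of 36 positive, adjusted p = 0.00164). Dilution by T cell RNA cannot be told apart from other causes. Ferritin-iso had a lower T cell marker score than Ferritin-aCD4 (4.75 against 5.43, SD 0.30 and 0.08), and its interferon-stimulated list was lower too. The list's median was -0.40 there (adjusted p = 0.0289 by camera with an estimated correlation). The antibody also differs between these groups and can mask dilution, so the comparison cannot decide. In MICB-iso against Ferritin-iso, dendritic cell identity genes had a median of 0.64, in the same direction as the list's 0.97. With the T cell marker score as a covariate the median of the called genes went from 2.08 (median SE 0.32) to 1.93 (0.61) and 0 passed, so the calls ended mainly with the wider error. A response to the vaccine that needs CD4 cells stays open as a hypothesis. The interaction passed for the list (adjusted p = 0.000775 by camera with an estimated correlation). It also passed for cDC1, cDC2, and macrophage and monocyte markers, and a different mix of sorted cells was not tested.

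The second pattern is the higher Hspa1a and Hspa1b of isotype over anti-CD4 libraries, by 2.51 ± 0.21 and 2.93 ± 0.26 in dendritic cells and 3.03 ± 0.15 and 3.34 ± 0.14 in NK cells. Stress of tissue dissociation cannot be told apart: 18 immediate-early genes had a median of -0.00539 in dendritic cells and 17 had -0.12 in NK cells, going both ways, while the 4 other heat shock genes were all positive (medians 0.53 and 0.36), Hsph1 passed in both (1.32 and 0.92) and Cirbp was lower (-0.76, not past the threshold, and -0.85). Handling shared by the NK and dendritic cell libraries of 1 group and number called for an r over 0.58. Pearson's r over 12 pairs was -0.38 (jackknife SE 0.14) and Spearman's rho -0.59, under the bound of 0 set before the result. Permutation p was 0.223 and 0.0477 (100000 resamples across all 12 pairs, not within groups). The labels do not say that libraries of 1 number share a mouse or day. The values speak only to handling that follows the number and leave other shared handling open. Handling of whole groups is confounded with the antibody, and an effect of CD4 depletion is a further open hypothesis.

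The third pattern is the lower T cell transcripts in MICB-iso dendritic cells than in the control groups, with a list median of -1.12. A lower share of dendritic cells in the control libraries cannot be told apart either. B cell markers had a median of 0.30, plasma cell markers 1.29 and NK identity genes 0.46, while stromal markers had -0.84. Of these lists only the stromal markers were thus higher in the controls. A share lowered by T cells alone need not raise them, so they cannot decide. Dendritic cell identity genes had a median of 0.64 in MICB-iso against Ferritin-iso. RNA of T cells in the sort cannot be told apart from other causes, since the 12 T cell markers had a mean pairwise r of 0.161 within groups, just above the upper limit of 0.156 of 1000 random sets.

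Other splits of the same libraries bear on the counts of genes. In dendritic cells 1 of 61 splits, the real one, was as large for MICB-iso against the control groups (97 genes, highest other 4). The same held for the interaction (8 genes, 1 of 61, highest other 3). These splits shuffle all 4 groups, so real differences between any groups widen the spread within the other splits. A share under 0.05 therefore speaks only against all 4 groups being alike, and chance is not excluded for either comparison. In NK cells the shares for the same comparisons were also under 0.05. They were 2 of 61 for 129 genes (highest other 325) and 3 of 61 for 10 genes in the interaction (highest other 37). The splits were drawn and 3 of 61 is close to that limit, so chance is not excluded here either. Those other counts point to a structure of the samples beside the groups, whose source was not tested. The split of 325 genes set Ferritin-aCD4 replicates 1 and 2 and MICB-aCD4 replicate 3 against the rest. Pairwise comparisons have 10 splits, too few for a share under 0.05: MICB-iso against Ferritin-iso gave 75 genes in dendritic and 43 in NK cells, against MICB-aCD4 12 and 14, and Ferritin-iso against Ferritin-aCD4 3 and 56, each with 1 split as large and a highest other of 0. For MICB-aCD4 against Ferritin-aCD4 the 0 genes in dendritic cells by edgeR (1388 at an unadjusted p under 0.05, DESeq2 5, limma voom 2) were met by 10 of 10 splits, and the 20 in NK cells by 2 of 10, the highest other being 197 with the same 3 libraries set apart.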

How the results depend on the processing

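The T cell marker covariate, the removal of the libraries with fewest detected genes, of cluster 18 and of the highest Scrublet scores, and camera with an estimated correlation under the block were added after the data were seen, as was the rule that kept thin single-cell counts out. Counts below are in the order MICB-iso against Ferritin-iso, against MICB-aCD4, Ferritin-iso against Ferritin-aCD4, MICB-aCD4 against Ferritin-aCD4, MICB-iso against the 3 controls, and the interaction. The cause of a change was not tested unless stated. RLE size factors kept all 12 counts within 1.5 times. DESeq2 gave 335, 260, 126, 5, 475 and 138 genes in dendritic cells and 227, 106, 410, 83, 451 and 66 in NK cells; limma voom gave 473, 189, 76, 2, 537 and 90, and 194, 297, 113, 97, 1004 and 67. Without a low-count filter, which changes the genes tested, the counts were 239, 156, 161, 54, 302 and 163, and 155, 83, 575, 114, 359 and 63. A fold minimum of 1.5, a stricter test by construction, gave 11, 2, 3, 0, 4 and 4, and 2, 2, 2, 0, 5 and 0. Fits of the 6 libraries compared gave 294, 50, 2 and 0 in dendritic and 22, 296, 3 and 5 in NK cells for the pairwise comparisons. With the controls pooled as 1 group 25 and 31 genes passed. With the T cell marker score 0, 0, 0, 0, 0 and 0 genes passed in dendritic cells by edgeR and 21, 16, 2, 22, 105 and 3 in NK cells, and Kdr turned to -0.0412. Without the libraries with fewest detected genes the counts were 266, 109, 16, 0, 215 and 41, and 226, 247, 114, 57, 766 and 51.

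Replicate numbers did not pair the libraries: same-number correlations ran from -0.118 to 0.118 in dendritic cells and from -0.396 to 0.124 in NK cells, 1 of 18 pairs in each exceeded 0.1, and 3 and 1 of 12 libraries correlated best with their own number. With the replicate number as a block the counts were 53, 2, 4, 0, 57 and 3 in dendritic cells and 20, 5, 31, 11, 77 and 3 in NK cells. Of 185 list calls 174 held with the block and 11 did not; with an estimated correlation 27 held, with both 10, and with fry 96.

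Leaving out each library in turn gave 4 to 457, 2 to 183, 2 to 23, 0 to 0, 5 to 453 and 3 to 62 genes in dendritic cells and 11 to 122, 4 to 47, 25 to 57, 5 to 32, 21 to 302 and 3 to 16 in NK cells; 83 of 144 counts moved by over 1.5 times. In dendritic cells MICB-iso against Ferritin-iso gave 457 without Ferritin-aCD4 replicate 3, 18, 4 and 25 without Ferritin-iso replicates 1, 2 and 3, 46 and 44 without MICB-aCD4 replicates 1 and 3, and 12 and 28 without MICB-iso replicates 2 and 3. Against the 3 controls it gave 453 without Ferritin-aCD4 replicate 3, 53, 55 and 56 without Ferritin-iso replicates 1, 2 and 3, 58 and 44 without MICB-aCD4 replicates 1 and 3, and 42, 5 and 31 without MICB-iso replicates 1, 2 and 3. In NK cells MICB-iso against Ferritin-iso gave 122 without Ferritin-aCD4 replicate 1, 18 and 15 without Ferritin-iso replicates 2 and 3, 28 without MICB-aCD4 replicate 1, and 12, 12 and 11 without MICB-iso replicates 1, 2 and 3. Against the 3 controls it gave 302 and 80 without Ferritin-aCD4 replicates 1 and 2, 207 without Ferritin-iso replicate 1, 75 and 77 without MICB-aCD4 replicates 1 and 3, and 26, 24 and 21 without MICB-iso replicates 1, 2 and 3.

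Of 193 named bulk results, 193 kept their direction and call with DESeq2, 192 with limma voom, 189 without a filter and 186 with RLE. With the block 128 did so, with the T cell marker score 68, and over the left-out libraries 1585 of 2316. The fold minimum of 1.5 kept 32, pooled controls 32 of 90 and fits of the 6 libraries compared 75 of 93. Cells with at least 2000 UMIs raised the MICB vaccine + dox shares to 10.3% (NK), 17.8% (CD8) and 22.3% (CD4) and the control vaccine + dox CD8 share to 6.51%. Cells called from marker UMIs gave CD8 shares of 6.87% in control vaccine + PBS, 7.5% in control vaccine + dox and 19.5% in MICB vaccine + dox, and CD4 shares of 3.51% and 16.7% in the dox libraries. Without cluster 18 the CD4 share of MICB vaccine + dox was 14.7%. A limit of 10% mitochondrial UMIs removed 0 cells and so tests nothing. Thinning cells to 1000 UMIs reversed Ccl5 (-0.0027, over MICB vaccine + PBS) and Klrk1 (-0.47, over control vaccine + PBS) in CD8 cells, and Pdcd1 (0.44, over control vaccine + dox) and Ifng (-0.26, over control vaccine + PBS) in CD4 cells; Ifng was -0.0739 without the highest Scrublet scores. Of 110 thinned levels 53 stayed within their interval. Clonotypes of at least 3 cells held 11.5%, 35.7%, 12.9% and 42.6% of receptor cells in control vaccine + PBS, control vaccine + dox, MICB vaccine + PBS and MICB vaccine + dox. Cells with both chains gave 46.9% and 52.3% in the dox libraries, annotated T cells alone 10.8% in MICB vaccine + PBS, and thinning to 451 cells 37.0% in MICB vaccine + dox.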

Other observations

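The gene lists below were fixed before the data were examined, but which of them are given here was chosen after their values were seen. In dendritic cells of MICB-iso against Ferritin-iso, of 30 maturation and migration genes 1 rose by edgeR, Cd86, and Cd80 rose adjusted over the list alone (list median 0.16, adjusted p = 0.271 by camera with an estimated correlation). Of 19 regulatory molecules 2 rose, Pdcd1lg2 and Cd200, and 4 adjusted over the list alone, with Cd274 and Socs3 added (median 0.44, adjusted p = 0.0847 with an estimated correlation). Of 24 cytokine genes acting on NK and T cells 2 rose, Cxcl9 and Cxcl10, and 6 adjusted over the list alone, with Il18, Ccl4, Ccl8 and Il1b added (median 0.22, adjusted p = 0.280 with an estimated correlation). Each list passed with camera's preset correlation.

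In tumours, the interferon gamma response list of cells annotated Neu had a median log2 ratio of 1.41 in MICB vaccine + dox over control vaccine + dox, 2.16 over MICB vaccine + PBS and 1.48 over control vaccine + PBS. The Neu cells were not matched by cluster: the largest share lay in cluster 2 in MICB vaccine + dox (50.7%) and control vaccine + PBS (52.7%) and in cluster 7 in control vaccine + dox (49.0%) and MICB vaccine + PBS (53.5%), and a change of cluster mix was not separated from a change within clusters. Neu cells were 9.76% of annotated cells against 12.7%, 6.52% and 11.0% in these libraries. In CD4 T cells, interferon-stimulated genes had a median of -0.39 over control vaccine + dox, -0.09 over MICB vaccine + PBS and -0.45 over control vaccine + PBS, and in NK cells 0.05 over control vaccine + dox and 0.45 over control vaccine + PBS. In CD8 T cells the interferon gamma response list had medians of 0.19, 0.55 and 0.04 over control vaccine + dox, MICB vaccine + PBS and control vaccine + PBS. With 1 library per group none of these tumour values was tested.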
